A study of Homo sapiens with 10 samples.

How the data were processed

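DNA methylation was measured by enhanced reduced representation bisulfite sequencing, in which DNA is cut by a restriction enzyme, size-selected for fragments rich in CpG sites, treated with bisulfite and sequenced, so that an unmethylated cytosine is read as T and a methylated cytosine as C. The 10 samples came from 2 human embryonic stem cell lines. HUES8 was represented by wild-type cells (WT), cells with inactivating mutations in TET1, TET2 and TET3 (TKO) and cells with inactivating mutations in the same 3 genes and DNMT3B (QKO). MEL1 was represented by WT and TKO cells. Each group held 2 samples. TET1, TET2 and TET3 encode dioxygenases that oxidise 5-methylcytosine, and DNMT3B encodes a de novo DNA methyltransferase. The growth protocol in the labels describes HUES8 cells on mouse embryonic fibroblast feeders, and whether reads from feeder DNA were removed is not given in the sources used here.

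For each MEL1 library the authors deposited 1 table of cytosines in CpG sites, with the coverage as a read count and the percent of reads showing C or T, per the file headers. The lowest count in each of these tables was 10 reads per site. Submitters' processing notes name CASAVA 1.8.2 for MEL1 and Bismark 0.13.0 for HUES8, and the build hg19 for both lines. The aligner and methylation caller for MEL1 and the caller of the HUES8 regions are not given in the sources used here. Coverage multiplied by percent C gave a whole number of methylated reads at 100% of sites, within the rounding error of percent values printed with 3 decimals, so methylated and unmethylated counts were recovered from the deposited percent values. C and T together made up 100% of the reads at 98.5% of the sites in every library, and the remaining sites held other bases. Methylation is given as percent of reads, and differences are given in percentage points (points).

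For HUES8, 6 tables of regions from the authors' deposited comparisons were used, 2 for each pair of genotypes (numbered 1 and 2 by the authors, and called the first and the second table here). They give, per region, position, a number of CpG sites and the signed difference of mean methylation, which was multiplied by 100 to give points. Every region in the deposited tables had an absolute difference of at least 10.0 points and at least 5 CpG sites. No p-value, read count, level or library is attached to a region, so the depth behind the HUES8 values is unknown, and regions that were tested without reaching the tables are not known either. What the numbers 1 and 2 stand for is not stated in the sources used here. The sign is not stated either. With differences read as the first-named minus the second-named genotype, the QKO minus WT difference equalled the sum of the other 2 differences with a median residual of 2.44 points over 1439 regions found in all 3 comparisons (the first table, overlap of at least 50% of both regions). With the sign of the QKO and TKO table turned, the median residual was -38.3 points. A turn of all 6 tables together would leave this sum unchanged. Of 8066 regions of the TKO and WT table that were called in MEL1, 99.5% had the same sign in MEL1 under this reading, which was therefore used. The overall direction of the HUES8 changes was thus set with MEL1 and is no independent evidence that both lines moved the same way. Another 2 tables of the whole series, with 6 value columns, name no sample and were not used.

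MEL1 sites on the 22 autosomes with at least 10 reads in all 4 libraries (2356269 sites, strands separate) were used. Counts were summed over tiles of 1000 bp with at least 5 sites, which left 103204 tiles with a median of 10 sites and 710 reads per library. A design written before the data were examined had placed the counts in gene promoters. No annotation of hg19 was used here, and coordinates were not converted between builds, so tiles took the place of promoters, regions are named by hg19 position (counted from 1), and 13 gene lists, genes fixed by name and genomic context were not tested. Tiles were tested with a quasi-binomial logistic model with genotype as the only term, a dispersion moderated across tiles by limma's squeezeVar function and not allowed under 1, and an F test, two-sided, with Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 10 points. HUES8 regions holding at least 5 MEL1 sites were tested in MEL1 in the same way, with the regions of each deposited table as 1 family. The tiles named in the text are the 10 with the largest rise and the 6 with the largest fall among called tiles whose TKO libraries both lay on the same side of both WT libraries. For each HUES8 comparison, the same numbers of regions were taken from those found in both tables with the same sign, ranked by the mean of the 2 differences.

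Overlap between regions meant at least 1 shared base. Shares carry exact Clopper-Pearson 95% confidence intervals, which cover counting error only, since reads carry no molecular identifiers and neighbouring regions are not independent. Differences between sets of regions were computed chromosome by chromosome and tested with a two-sided permutation test that flips the sign of each chromosome's difference (100000 resamples). Overlap of tile lists was tested with Fisher's exact test, which treats tiles as independent and so gives p-values that are too small. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Genotypes were not replicated across separately derived clones as far as the labels show.

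The depth of the MEL1 libraries was about 204220000 to 216052000 reads summed over sites, with a median of 60 to 63 reads per site. Within a group, site counts differed by more than binomial sampling (chi-square per degree of freedom 2.60 for WT and 2.01 for TKO, over sites at 10 to 90% methylation), so no library was a copy of another. The test was also run on simulated data for MEL1 TKO and WT, made from the real reads and moderated dispersions of 103204 tiles with 200 changed tiles. It called 27 of 50 tiles changed by 15 points, 38 of 50 changed by 25 points and 49 of 50 changed by 40 points. It also called 8 of 50 tiles changed by -9 points, the only simulated fall, although that change is under the minimum of 10 points, and 1 of 103004 unchanged tiles. In the same simulation limma on levels called none of the changed tiles, while on the real data limma on mean site levels called 13862 higher tiles. The simulation changed far fewer tiles than were called in the data, which makes the adjusted p harder to reach. The changed tiles were also drawn only from intermediate WT levels, and the counts were drawn with the dispersions that the test itself had moderated. The simulated shares therefore do not give the power of either test, or its rate of false calls, on the real data. The limma calls are used as an alternative only.

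Alternatives fixed before the data were examined were a coverage minimum of 20, tiles of 500 bp, at least 10 sites, at least 20 points or no minimum difference, limma on mean site levels, edgeR's quasi-likelihood test on methylated and unmethylated counts, limma on log2 ratios of these counts with a pseudocount of 1, chromosome X included, sites above the 99.9th percentile of coverage left out, the replicate number as a block, and each replicate left out. For the region tables they were a stricter overlap, larger differences, more CpG sites and crossed table numbers. Tests across HUES8 libraries, a test of the difference between the lines, and simulated shared controls for HUES8 were not run, because HUES8 values per library were not analysed here. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16, data.table (version 1.17.8) and jsonlite 2.0.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.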

Results

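Methylation was profiled at CpG sites in HUES8 and MEL1 human embryonic stem cells that carried all 3 TET genes (WT) or inactivating mutations in TET1, TET2 and TET3 (TKO). HUES8 was also profiled with an added mutation of DNMT3B (QKO). Each of the 5 groups held 2 samples. The 4 MEL1 libraries covered 2522188 to 2705209 cytosines in CpG sites at 10 or more reads, with about 204220000 to 216052000 reads summed over sites and a median of 60 to 63 reads per site. Site levels correlated at r = 0.987 between the WT libraries and r = 0.991 between the TKO libraries, against 0.934 to 0.939 between genotypes, across 2356269 sites that are not independent of one another. Levels of single sites differed on average by 3.91 points between the WT libraries, by 3.48 points between the TKO libraries and by 7.47 to 7.95 points between genotypes. For HUES8 the values come from the authors' deposited tables of differing regions, with no level or depth per library.

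The first question was how the loss of the TET enzymes, which start the removal of methyl groups from DNA, changed methylation in MEL1. Methylation rose. The mean level over common autosomal sites was 40.5% ± 0.233 (SD, n = 2) in WT and 45.8% ± 0.0781 (SD, n = 2) in TKO cells, a difference of 5.28 points that exceeded the spread within either genotype. With 2 libraries per group the exact two-sided permutation test gave the largest separation possible, but its p cannot fall under 0.05 in this design. Sites above 90% made up 24.7 to 25.1% of all sites in the WT libraries and 34.1 to 34.6% in the TKO libraries, while sites below 10% made up 51.9 to 52.2% and 46.5%.

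Of 103204 tiles, 15338 (14.9%) were higher in TKO and 884 (0.857%) were lower, by the quasi-binomial test with Benjamini-Hochberg adjustment. The median rise of the higher tiles was 23.5 points, and 5947 of them rose by 30 points or more. The share of tiles that rose depended on the starting level. Among tiles at 10 to 30% in WT library 1, 73.6% rose, and among those at 30 to 70%, 57.2% rose. Of tiles at 0 to 10%, 16.3% rose, and of those at 70 to 90%, 13.2% rose. Above 90% in WT library 1, 0.0674% of 34126 tiles rose, where a rise of 10 points is out of reach for nearly all tiles. The class came from WT library 1 alone. Read against WT library 2, the mean gain of the tiles at 10 to 30% was 34.4 points, and that of the tiles at 0 to 10% was 6.68 points with a median of 0.447 points. Gains from a low level were common in number, with 6113 higher tiles (39.9%) starting below a mean WT level of 20%, and 2089 of these ended above 50%.

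**Figure D1:**
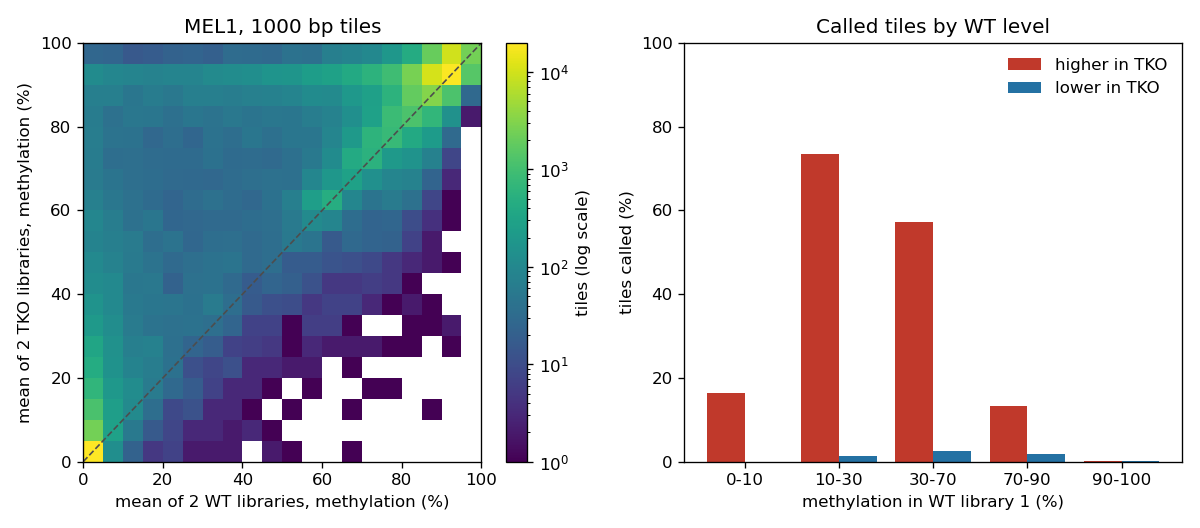
Methylation of 1000 bp tiles in MEL1 WT and TKO cells. The left panel counts tiles (log colour scale) by the mean level of the 2 WT libraries (horizontal axis, percent) and of the 2 TKO libraries (vertical axis, percent), with a dashed line where both are equal; most of the tiles away from the line lie above it. The right panel gives the percent of tiles called higher (red) or lower (blue) in TKO by the level in WT library 1 (percent), with 73.6% higher in the class from 10 to 30%.

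The tiles with the largest rise went from nearly unmethylated to nearly fully methylated. On chromosome 12, the tile from 109549001 to 109550000 rose from 1.37% ± 0.422 to 98.6% ± 2.04 (SD, n = 2 per genotype; adjusted p = 1.12e-06, quasi-binomial test moderated with limma), with 76 to 187 reads per library over 6 sites. On chromosome 1, the tile from 44015001 to 44016000 rose from 0.146% ± 0.207 to 96.3% ± 0.662 (adjusted p = 6.07e-08, limma-moderated). The tile on chromosome 19 from 10464001 to 10465000, with 23 sites and 2429 to 3506 reads per library, rose from 1.30% ± 0.252 to 96.0% ± 0.119 (adjusted p = 1.45e-10, limma-moderated). The tile on chromosome 10 from 94451001 to 94452000, with 26 sites, rose from 1.72% ± 0.0963 to 95.7% ± 1.21. On chromosome 12 the tile from 53359001 to 53360000 rose from 1.02% ± 0.0523 to 95.5% ± 0.547, and the tile from 85672001 to 85673000 rose from 2.45% ± 1.83 to 96.6% ± 1.45. On chromosome 11 the tile from 76858001 to 76859000 rose by 94.2 points and the tile from 73357001 to 73358000 by 94.0 points. The remaining tiles of the 10 lay on chromosome 1 (155290001 to 155291000, 94.3 points) and chromosome 5 (124071001 to 124072000, 94.0 points). In HUES8, 8 of these 10 tiles overlapped a region listed as higher in TKO in both of the authors' deposited tables, and the tiles on chromosome 1 from 44015001 and chromosome 10 from 94451001 overlapped none.

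Large falls were rarer. The largest was on chromosome 8, where the tile from 57358001 to 57359000 (88 sites, 4761 to 7221 reads per library) fell from 85.8% ± 0.107 to 10.6% ± 1.14 (SD, n = 2 per genotype; adjusted p = 1.96e-10, limma-moderated). The tile on chromosome 4 from 87396001 to 87397000 fell from 65.9% ± 1.35 to 0.529% ± 0.748 over 5 sites. Tiles on chromosome 14 fell from 90.7% ± 0.117 to 29.7% ± 0.0293 (86204001 to 86205000) and from 90.6% ± 0.951 to 30.5% ± 4.71 (106146001 to 106147000). On chromosome 12 (14927001 to 14928000) the level fell from 94.0% ± 2.39 to 33.2% ± 2.24, and on chromosome 5 (35925001 to 35926000) from 76.2% ± 0.972 to 16.8% ± 0.122. Of the chromosomes, 19 held the highest share of lower tiles, 2.35% of 8100, and also the highest share of higher tiles, 17.8%. The number of lower tiles depended on the test and was 495 with limma on log2 ratios.

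The same knockout was made in HUES8, and the authors' deposited tables list changes almost all of 1 sign. The files do not state the sign, which was read as a gain because MEL1 gained, so the shared direction is not a finding. On the autosomes, the first table holds 11019 regions higher and 164 lower in TKO than in WT, and the second table holds 10907 higher and 170 lower. The median gain in the first table was 35.6 points over regions with a median width of 223 bp and 15 CpG sites (width and sites over both directions), and 3346 regions (30.4% of the higher ones) gained more than 50 points. The higher regions covered 3.30 Mb. Of the higher regions of the first table, 90.3% (95% CI 89.7 to 90.8%) overlapped a higher region of the second table, and their differences in the authors' deposited tables were 3.30 points apart on average. Of the lower regions 70.7% (95% CI 63.1 to 77.6%) were found again.

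**Figure D2:**
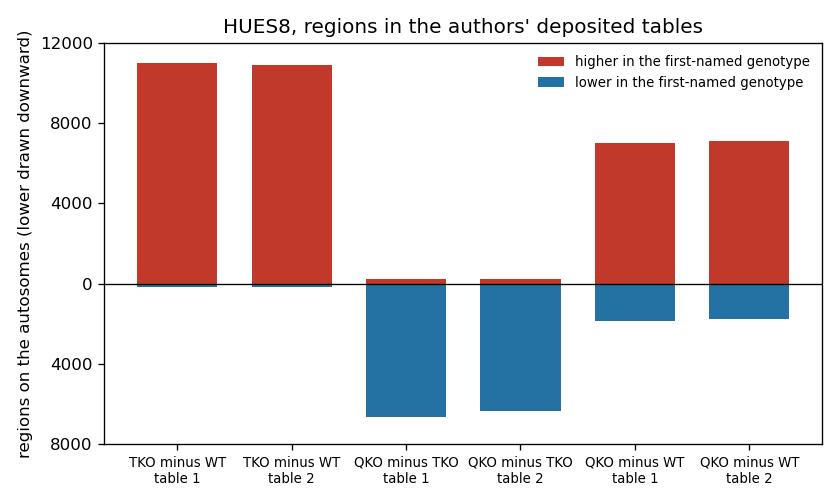
Number of regions on the autosomes in each of the authors' deposited tables for HUES8. Bars upward (red) count regions with higher methylation and bars downward (blue) regions with lower methylation in the genotype named first; TKO minus WT is almost all upward, QKO minus TKO almost all downward, and QKO minus WT has 6992 upward and 1859 downward in the first table.

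The largest HUES8 gains in the authors' deposited tables reached about the full scale. On chromosome 17 a region of 7 CpG sites from 16650051 to 16650093 gained 94.8 points in the first table and 95.1 points in the second table. On chromosome 20, 32 CpG sites from 7784445 to 7784576 gained 93.5 and 91.5 points, and on chromosome 12, 53 CpG sites from 8025292 to 8025886 gained 91.3 and 92.2 points. A region on chromosome 6 from 10660089 to 10660306 gained 91.8 and 92.0 points. A region on chromosome 7 from 6793803 to 6793839 gained 90.4 and 92.6 points, and another from 9661353 to 9661494 gained 91.9 and 90.7 points. The remaining regions of the 10 lay on chromosome 1 (149674198 to 149674242), chromosome 3 (145051359 to 145051382), chromosome 9 (93955741 to 93955765) and chromosome 10 (131904232 to 131904272), with 94.1, 93.3, 92.1 and 92.2 points in the first table of the authors' deposited tables. The region with the most CpG sites found in both tables was on chromosome 10 from 134597943 to 134602649, with 607 CpG sites over 4707 bp and a gain of 55.8 points in the first table. Falls in the authors' deposited tables were led by chromosome 4 from 87396655 to 87396703, at -66.7 and -74.8 points, and by chromosome 19 from 57049676 to 57050518, where 124 CpG sites differed by -52.6 and -51.6 points. They also included chromosome 18 from 68879999 to 68880048 (-43.4 points in the first table), chromosome 6 from 58287803 to 58287827 (-46.4 points), chromosome 22 from 19928909 to 19929624 (-45.4 points) and chromosome 16 from 87900671 to 87901046 (-41.3 points).

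With the sign of the HUES8 tables set by MEL1, the comparison of the lines concerns which regions changed and not the overall direction. Of 10465 HUES8 regions of the first table that were measured in MEL1, 76.1% (95% CI 75.2 to 76.9%) were called higher in MEL1 TKO and 0.258% were called lower, with a median MEL1 difference of 26.8 points. The median level of these regions was 19.4 and 17.8% in the MEL1 WT libraries and 78.5 and 78.9% in the TKO libraries. By tiles, 7287 of the 15338 tiles higher in MEL1 overlapped a gain found in both HUES8 tables, against 1676 if the lists were independent (Fisher's exact test, p below 1e-300). Both lists depend on the starting level, and with independence only within 5 classes of the MEL1 WT level 3565 were expected. Of tiles that overlapped a gain found in both HUES8 tables, 64.6% were called higher, against 8.76% of the other tiles. Tiles outside every HUES8 region were called higher at 7.86% of 89758. These shares are by tile and are not on the same footing as the 76.1% by region. The sizes of the gains were weakly related across regions, which are not independent replicates (Pearson r = 0.208, Spearman rho = 0.199).

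Whether a HUES8 gain was also called in MEL1 went with the MEL1 WT level. It was called in 95.7% of 1983 regions at 10 to 30% in MEL1 WT, in 95.2% of 2072 regions at 30 to 70%, and in 82.1% of 4155 regions at 10% or less. At 70 to 90% it was called in 46.6% of 1454 regions. Above 90% it was called in 0 of 801 regions, where the remaining room was under 10 points. Of 2479 regions with no call in either direction, 63.0% lay at 70% or more in MEL1 WT. The largest HUES8 gains included both kinds. The region on chromosome 7 from 6793803 rose from 5.80% ± 3.31 to 95.6% ± 0.515 in MEL1 (SD, n = 2 per genotype), and that on chromosome 6 from 10660089 rose from 29.4% ± 4.49 to 91.7% ± 1.54. The region on chromosome 20 from 7784445 stood at 94.4% ± 0.417 in MEL1 WT and 96.5% ± 1.74 in MEL1 TKO, and that on chromosome 12 from 8025292 at 93.5% ± 0.672 and 96.7% ± 0.0481. The region with 607 CpG sites on chromosome 10 rose by 8.43 points in MEL1, from 13.3% ± 0.780 to 21.7% ± 0.285, less than the 10 points needed for a call. The difference between the lines was not tested, since no HUES8 values per library were used here.

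Of 155 HUES8 regions lower in TKO that were measured in MEL1, 63 (40.6%) were called lower and 17 were called higher. By tiles, 47 of the 884 tiles lower in MEL1 overlapped a fall found in both HUES8 tables, against 1.11 if the lists were independent (Fisher's exact test, p = 6.57e-63). Of the 6 largest HUES8 falls named above, only that on chromosome 4 was called lower in MEL1. The region on chromosome 19 from 57049676 was called higher there, from 37.1% ± 1.84 to 49.1% ± 0.934 (SD, n = 2 per genotype; adjusted p = 3.02e-07, limma-moderated). Those on chromosomes 18, 6 and 22 were not called, with differences of -0.880, -0.222 and 1.71 points, and that on chromosome 16 was not measured. The fall on chromosome 4 was in the region on chromosome 4 from 87396655 to 87396703, which went from 65.9% ± 1.35 to 0.529% ± 0.748 in MEL1 (SD, n = 2 per genotype; adjusted p = 1.23e-07, limma-moderated). On chromosome 12 a region from 34778189 to 34778262 differed by -36.6 points in the first table of the authors' deposited tables and fell from 37.0% ± 1.74 to 3.15% ± 2.23 in MEL1. On chromosome 14 a region from 106478007 to 106478041 differed by -31.2 points in the first of the authors' deposited tables and fell from 48.6% ± 1.34 to 5.86% ± 0.0280 in MEL1. These last 2 regions were chosen after their values were seen.

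The QKO cells ask how much of the TKO gain was present when DNMT3B was mutated as well. Against TKO, the first of the authors' deposited tables lists 6664 regions lower and 216 higher in QKO, and the second table lists 6341 lower and 222 higher. The median difference of the lower regions in the first table was -21.5 points. Lower regions of the first table overlapped lower regions of the second table in 80.6% of cases (95% CI 79.7 to 81.6%). Of the regions that gained in TKO, 41.0% (95% CI 40.1 to 41.9%) overlapped a region lower in QKO than in TKO, and the median loss there was 78.1% of the gain. This median covers only regions listed with a loss of at least 10 points, which small gains reach only by losing much of their size, so it does not describe all gains. By tiles with MEL1 coverage, 4399 were in both lists (gain in TKO, lower in QKO), against 684 if the lists were independent, and part of that excess may come from the TKO libraries that both comparisons share. At the same time 61.1% of the TKO gains overlapped a region higher in QKO than in WT (comparisons that share the WT libraries), where a median of 88.1% of the gain was left, again among listed regions only. Gains fell into 4 classes by the authors' deposited tables. In QKO 2183 regions (19.8%) were lower than TKO and still above WT, 2334 (21.2%) were lower and not listed above WT, 4553 (41.3%) were above WT and not listed as lower, and 1949 (17.7%) were in neither list. A region missing from a table was not shown to be unchanged.

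These classes differed in their MEL1 level. Regions lowered in QKO had median levels of 10.7 and 9.45% in the MEL1 WT libraries where still above WT, and 7.93 and 6.97% where not. Regions above WT and not lowered had medians of 37.1 and 35.0%. The MEL1 TKO medians were 63.3 and 63.5%, 46.4 and 46.0%, and 89.9 and 90.5% in the same order. Averaged over chromosomes, the MEL1 WT level of lowered gains was 23.1 points below that of gains above WT and not lowered (SD 4.59 over 22 chromosomes, lower in 22 of 22). The permutation test gave p = 1e-05, the smallest that it can give. Median gains in HUES8 TKO were 43.7, 22.2 and 49.2 points in the 3 classes, and the classes with both listings held more CpG sites, with a median of 30 against 14 and 15.

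**Figure D3:**
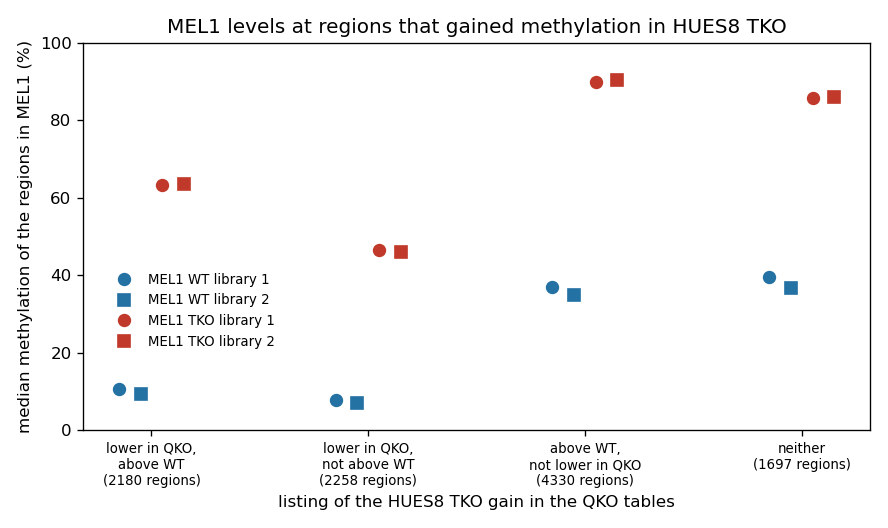
Median methylation (percent, vertical axis) in each MEL1 library of regions that gained methylation in HUES8 TKO, grouped by how the QKO tables list them (the first table for both). Blue symbols are the 2 WT libraries and red symbols the 2 TKO libraries; regions lower in QKO sit at 6.97 to 10.7% in MEL1 WT, and regions above WT that are not lower in QKO at 35.0 to 37.1%.

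The single regions named next have large differences of QKO from TKO or from WT in the authors' deposited tables. A listed TKO gain was not required. Of all regions lower in QKO than in TKO in the first table, 68.5% overlapped a TKO gain. On chromosome 17, 66 CpG sites from 55938754 to 55939497 differed by -66.3 and -69.0 points between QKO and TKO. In MEL1 this region rose from 2.04% ± 0.0528 in WT to 95.2% ± 0.937 in TKO (SD, n = 2 per genotype). On chromosome 12 the region from 109549000 to 109549042, inside the tile with the largest MEL1 rise, differed by -68.4 and -63.6 points between QKO and TKO. On chromosome 2 from 119591176 to 119591705 the differences were -66.8 and -66.6 points, and on chromosome 14 from 103593624 to 103593724 they were -67.4 and -66.9 points. The other regions of this list lay on chromosome 17 (46672208 to 46672379, -66.5 points in the first table) and chromosome 1 (110230286 to 110230430, -65.8 points). In the authors' deposited tables the gain on chromosome 20 from 7784445 was listed at 92.6 and 90.3 points in QKO against WT, and that on chromosome 1 from 149674198 at 89.9 and 93.8 points. On chromosome 3, 93 CpG sites from 194406441 to 194407135 were 89.5 and 88.5 points higher in QKO than in WT, while in MEL1 they stood at 0.467% ± 0.182 in WT and 0.427% ± 0.0212 in TKO. On chromosome 12 from 85672288 to 85672521 the QKO gain over WT was 85.9 and 91.1 points, and in MEL1 the region rose from 2.45% ± 1.83 to 96.6% ± 1.45.

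A small set of regions was higher in QKO than in TKO in the authors' deposited tables. Of the 216 regions in the first table, 82.4% overlapped a TKO gain and 96.8% were also above WT, in comparisons that share the TKO or the QKO libraries, and the overlap that this sharing alone would give was not computed. The largest difference was on chromosome 4 from 48908255 to 48908942 (46 CpG sites), at 84.9 and 81.5 points. The next was the chromosome 4 region from 87396655, lower in TKO, where QKO exceeded TKO by 74.5 and 68.4 points and no QKO and WT region was listed. Neighbouring regions on chromosome 1 (55505148 to 55505448 and 55505758 to 55505998) were 46.5 and 51.2 points higher in the first table. Regions on chromosome 9 (130590705 to 130590775), chromosome 7 (27204712 to 27205281) and chromosome 19 (38908574 to 38908640) were 52.1, 51.2 and 58.9 points higher in the first table of the authors' deposited tables. The list ended with chromosome 4 (165898586 to 165898826, 49.2 points), chromosome 7 (65037665 to 65037706, 44.0 points) and chromosome 1 (119542875 to 119543425, 46.9 points). The last lay in a 1 Mb window (119 to 120 Mb) that held 9 such regions found in both tables.

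Against WT, the authors' deposited tables list 6992 regions higher and 1859 lower in QKO (the first table), and 7097 and 1747 (the second table). Nearly all of the higher regions of the first table (96.9%) overlapped a TKO gain, but both comparisons share the WT libraries, and the overlap that this sharing alone would give was not computed. Of the lower regions of the first table, 76.7% (95% CI 74.7 to 78.6%) were found in the second table. By overlap, 68.0% of the lower regions were also lower than TKO, 8.34% were lower in TKO than in WT, and 11.2% were TKO gains. These comparisons share libraries of QKO or WT, so part of each overlap may come from chance values of the shared libraries. Their median difference in the first table was -24.6 points. In MEL1, which has no DNMT3B mutant here, their median levels were 57.9 and 55.8% in WT and 59.3 and 58.7% in TKO. The median of the differences per region was -1.54 points (-1.88 for the second table), so the medians of the levels do not show a rise. Of 1739 measured, 20.4% were called lower and 23.9% higher. The largest falls in the authors' deposited tables were on chromosome 22 from 16096133 to 16096364 (-70.1 and -65.5 points), chromosome 10 from 134036804 to 134036905 (-67.0 and -65.1 points) and chromosome 14 from 106360333 to 106360561 (-63.4 and -67.9 points). Others were on chromosome 9 from 105876604 to 105876815 (-66.6 and -63.5 points), chromosome 16 from 33514124 to 33514276 (-60.0 and -66.7 points) and chromosome 14 from 20519685 to 20519746 (-63.2 and -60.7 points). In MEL1 TKO the chromosome 16 region fell from 76.6% ± 2.39 to 41.7% ± 1.39 (SD, n = 2 per genotype), the chromosome 9 region fell to 25.4% ± 1.36 (a difference of -34.6 points), and the chromosome 10 region from 34.6% ± 2.92 to 16.2% ± 3.03.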

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

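The tests in this part on chromosome M, on crossed tables, on matched regions and on the position of methylated sites were chosen after the result was seen, and those on thinned reads, on reads per site and on losses shared with MEL1 TKO were also added after the data were seen, though before their own outcome was known. Some regions moved in opposite directions in the 2 lines under the same knockout, given the sign read from MEL1, and this difference was not tested, since no HUES8 values per library were used here. There were 25 regions, of 9567 measured, that were higher in both HUES8 TKO tables while both MEL1 TKO libraries lay below both MEL1 WT libraries and the fall was called. The opposite pattern held for 12 of 112 regions. The 3 regions with the largest MEL1 falls lay on chromosome 18 from 14179084 to 14179125 (MEL1 difference -83.3 points, and 51.4 points in the first table of the authors' deposited tables), chromosome 8 from 57358148 to 57359273 (-68.5 points, and 18.2 points over 144 CpG sites) and chromosome 19 from 12443722 to 12444302 (-49.8 points, and 40.7 points). The 3 with the largest MEL1 rises among HUES8 falls lay on chromosome 15 from 90291071 to 90291142 (63.7 points, and -23.3 points in HUES8), chromosome 19 from 20278004 to 20278343 (52.1 points, and -10.3 points) and chromosome 17 from 44894203 to 44894387 (36.8 points, and -29.2 points). No explanation of these opposite changes was tested.

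The rise of methylation in MEL1 TKO was weighed against faults of the libraries. Incomplete bisulfite conversion would leave cytosines of every sequence looking methylated, but the level over chromosome M was 0.119 points lower in the TKO libraries (mean difference -0.119 points; 0.245 to 0.248% in TKO and 0.260 to 0.472% in WT). At all 10 tiles with the largest rise, both TKO libraries had fewer reads than both WT libraries. At the named falls the TKO libraries had more reads on average, except on chromosome 4. On chromosome 8 the TKO libraries had more reads (6910 and 7221 against 4982 and 4761 in WT). They also had more on chromosome 5 (1886 and 2467 against 1140 and 1368) and chromosome 12 (3403 and 3971 against 3145 and 3220). On chromosome 14 the counts were 451 and 455 against 314 and 234 (from 86204001), and 339 and 216 against 228 and 183 (from 106146001). On chromosome 4 they had fewer on average (189 and 145 against 214 and 172). Apart from that tile, mean reads thus moved opposite to methylation at all named tiles. With the reads of each tile thinned to the same number in all 4 libraries, 96.6% of the higher tiles were still called. The unequal number of reads alone therefore did not give the calls. Thinning draws reads at random and leaves the expected level of a tile unchanged. It thus cannot show whether the recovery of fragments depended on their methylation, and that was not tested. The same knockout in HUES8 was listed in many of the same places, with 7287 tiles shared against 3565 expected within classes of the MEL1 WT level, which argues against a difference peculiar to the MEL1 cultures as the whole cause. The loss of the TET enzymes is the biological explanation that the design names, as a hypothesis, and differences that came with making knockout cells in both lines were not tested.

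The TKO gains that were lower in QKO had a low level in MEL1 WT. Both contrasts share the TKO libraries, so chance values of these libraries could make a gain and a loss in the same region. With the gain from the first table and the loss from the second table the difference in MEL1 WT level was -23.9 points, close to the -23.1 points from the first table alone, although whether the table numbers stand for separate libraries is not stated. In the MEL1 libraries, which are separate, 83.6 and 82.4% of the lowered gains (still above WT or not) were called higher in TKO. The share was 68.6% for gains above WT and not lowered, and 76.9% for gains in neither list. These shares also follow the MEL1 WT level. With no QKO cells in MEL1, the calls bear on the gain only. They cannot tell whether the listed loss came in part from chance values of the shared TKO libraries. Size of the gain and number of CpG sites also differed between the classes, but after matching on both the difference was -23.5 points. The MEL1 WT level is not the HUES8 WT level. The gains on chromosome 20 from 7784445 and chromosome 1 from 149674198, at 93.5 and 94.1 points in the authors' deposited tables, must have started low in HUES8, stood at 94.4 and 97.4% in MEL1 WT, and were listed at 92.6 and 89.9 points in QKO. Whether the starting level in HUES8 itself sets the dependence on DNMT3B stays open, and WT levels per HUES8 library at these regions would test it.

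A minority of the regions that lost methylation, larger than that of methylated tiles, lay near the longest stretch without a covered CpG site on each chromosome, which on most chromosomes marks the centromere (on chromosomes 13, 14, 15, 21 and 22 the start of the covered sequence was used). Of 1426 regions lower in QKO than in WT in both tables, 24.8% (95% CI 22.6 to 27.2%) lay within 5 Mb of it, against 6.08% of MEL1 tiles at 50% or more in WT. By chromosome the share was 20.4 points higher (higher on 21 of 22, permutation p = 1e-05, the smallest possible, adjusted p = 2.67e-05 over 8 tests). The placement of tiles methylated in MEL1 WT does not account for this. MEL1 tiles cannot exclude that HUES8 covered more methylated sites there, since its tested regions and WT levels are unknown. Tiles lower in MEL1 TKO showed the same placement (27.8% of 884). Against methylated tiles of the same line the share was 23.8 points higher by chromosome (higher on 19 of 22, permutation adjusted p = 2.67e-05 over 8 tests). Reads per site of these lower tiles near the stretch were 1.11 times those of the other methylated tiles nearby (95% bootstrap interval 1.07 to 1.18). This argues against a large pile-up of repeat reads confined to the lower tiles. A pile-up shared by both sets would not show in this ratio. QKO-lower regions near the stretch were called lower in MEL1 TKO more often than those elsewhere (37.3% of 327 and 17.7% of 1037). By chromosome the gap was 22.7 points (higher on 16 of 17, permutation p = 4.00e-05). Of the same regions, 5.50 and 27.8% were called higher. Part of this loss may thus arise in MEL1 without a DNMT3B mutation. The sets were not matched on the MEL1 WT level, so a different starting level was not excluded. All MEL1 lower tiles also favoured the stretch (27.8% against 6.08% of all tiles), so the gap need not be particular to QKO-lower regions. In HUES8, of the 354 regions near the stretch, 13.0% were listed as lower in TKO than in WT and 65.3% as lower in QKO than in TKO (9.51 and 77.0% of the 1072 regions elsewhere), and 29.9% were in neither list (18.4% elsewhere). A region missing from a list was not shown to be unchanged, the comparisons share the QKO or WT libraries, and 30.2% of the 116 regions lower in HUES8 TKO than in WT also lay near the stretch. How far the loss depends on DNMT3B stays open. Mapping of repeats in HUES8 and differences in culture history were not tested.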

How the results depend on the processing

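The thinned reads, the use of the second table in place of the first table and the stricter overlap for gains lowered in QKO were added after seeing the data. The MEL1 rise kept its direction under every alternative run, and the 16 named tiles kept direction and call in all 227 values that could be recomputed. These tiles were chosen for their large differences, and several settings leave the difference unchanged, so this is weak support. Only 11 of them could be recomputed at a coverage minimum of 20 and 8 with at least 10 sites. Tiles of 500 bp were not matched to them. The counts of tiles moved most with the definition of a call. Higher and lower tiles numbered 8936 and 240 at 20 points or more, 30184 and 1724 with no minimum difference, and 8558 and 290 with at least 10 sites per tile, where 53775 tiles were tested. Lower tiles numbered 495 with limma on log2 ratios, and the cause was not tested. Leaving out 1 replicate gave 13644 to 15673 higher tiles, 610 to 724 lower tiles and a mean difference of 5.11 to 5.44 points; with a lone library its spread was assumed to be that of the other group. The mean difference was 5.62 points with sites weighted by depth. Samples of the same replicate number shared no visible deviation across tiles (correlation -0.000236), which does not show that they were not prepared in pairs. With the replicate number as a block there were 15124 higher and 829 lower tiles and a mean difference of 5.28 points.

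The share of regions of the first table found in the second table, for TKO and WT, QKO and TKO, and QKO and WT, was 84.2, 73.0 and 82.2% with an overlap of at least 50% of both regions, 95.6, 86.9 and 94.1% for regions of at least 30 points, and 94.4, 85.5 and 93.7% for regions of at least 10 CpG sites. The share higher in the first-named genotype was 99.7, 4.12 and 87.7% at 30 points or more. With at least 10 CpG sites it was 98.9% for TKO and WT and 83.1% for QKO and WT, and for QKO and WT it was 80.2% in the second table. TKO gains lower in QKO made up 37.9% of gains of at least 20 points, 38.9% with the gain from the first table and the loss from the second table, 38.98% in the second table and 32.7% with the stricter overlap. The median percent of the gain lost was 66.4, 77.3, 78.1 and 79.3 in these settings, and 79.0 with the gain from the second table and the loss from the first table. The share of HUES8 gains called in MEL1 was 76.9% with limma on site levels, 75.2 to 76.4% with 1 replicate left out and 85.1% for regions under 20% in MEL1 WT, where r was 0.384 (0.205 to 0.211 with 1 replicate left out). The causes of these changes were not tested. Depth of HUES8 is unknown, and its alternatives on coverage, site levels, tiles and left-out replicates, as well as gene lists, were not run, because values per library and an annotation of hg19 were not used here.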

Other observations

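The tests in this part were chosen after the results were seen. TKO gains lay on every autosome. In HUES8, 81 gains found in both tables lay on chromosome 19 between 1 and 2 Mb, where 57 regions were lower in QKO than in TKO, and the MEL1 medians of these gains were 26.4% in WT and 78.3% in TKO. On chromosome 17 between 7 and 8 Mb, 48 gains had a median of 54.8 points in the first table. Relative to all covered tiles, whatever their level, gains were not concentrated at the ends. By chromosome, 5.22 points fewer of the HUES8 gains than of all MEL1 tiles lay within 5 Mb of an end (higher on 3 of 22 chromosomes; permutation p = 0.000150, adjusted p = 0.000300 over 8 tests). Tiles already methylated have little room to gain. Those at 50% or more in MEL1 WT lay near an end more often (34.2%) than all tiles did (28.4%). Gains were not compared with tiles of a low WT level, so their placement among tiles able to gain stays open.

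Some 1 Mb windows held many of the losses in QKO, though most losses lay outside the windows named here and clustering was not tested. On chromosome 1 between 2 and 3 Mb, 63 regions were lower in QKO than in WT in both tables, with a median of -31.7 points in the first table, in a window of 412 covered MEL1 tiles, and the MEL1 medians there were 82.8% in WT and 76.7% in TKO. On chromosome 14 between 106 and 107 Mb, 42 regions had a median of -39.7 points, with MEL1 medians of 78.1% in WT and 63.5% in TKO, and no TKO gain found in both tables lay in that window. On chromosome 16, 26 such regions lay between 34 and 35 Mb and 18 between 33 and 34 Mb, and on chromosome 12, 19 lay between 34 and 35 Mb together with 8 regions lower in TKO. On chromosome 8 between 143 and 144 Mb, 22 regions had a median of -31.2 points. The MEL1 medians of these windows did not all differ alike between WT and TKO. They were 85.1% in WT and 88.0% in TKO for the regions on chromosome 8 and 77.6 and 77.4% for those on chromosome 12. All are medians of levels, without the differences per region, so they do not show how single regions changed.

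Losses in QKO were also frequent near chromosome ends, with 39.3% of 1426 regions within 5 Mb of an end. The share was 34.2% for MEL1 tiles at 50% or more in WT and 21.9% for regions higher in QKO than in WT. By chromosome the difference from the methylated tiles was -0.298 points with an SD of 19.4 (permutation p = 0.944), which does not show that the shares were equal. From the regions higher in QKO it was 11.1 points (SD 18.8, higher on 17 of 22 chromosomes, adjusted p = 0.0165 over 8 tests). Whether losses are placed near ends beyond the placement of methylated DNA stays open.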
